A study of Mus musculus with 45 samples.

How the data were processed

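Bulk RNA sequencing was made from 45 cultures of differentiating mESCs, and per the series' design text they came from 3 independent differentiations. The labels do not say whether a replicate number marks a differentiation. The labels state the RA interval in 2 ways that differ by 1 day, and the day in each sample's title was used here. Libraries were made with a NuGEN mRNA kit and sequenced on a NovaSeq, per the labels' protocols. Picard, edgeR and the build mm10 are named in the submitters' processing notes without a role or version, and edgeR stands in the name of the authors' file. The aligner, the gene counter and the annotation are not given in the sources used here.

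The deposited table holds 11220 genes. Its normalized levels, deposited by the authors as a signal per gene and library, carry no unit in the header. They are not read counts: 0 are 0, and 1 is a whole number, counted with no tolerance on the values as deposited. Whole reads could not be recovered from them, so the depth of each library is unknown. At log2 levels of 1 to 2 the median SD between libraries of a group was 0.79 on the log2 scale. Counting would give 0.86 there if 1 unit of level were 1 read, which is not known. The columns headed fpkm, deposited by the authors, were treated as a score and not used as FPKM: each equals the level to the power 0.3 times a gene and a library constant (residual SD 0.0008 on the log2 scale). The deposited rank column, also a score, follows the mean level and was not used. The authors' deposited log2 fold changes followed ratios of the levels with slopes of 0.951 to 1.034 over 12 comparisons. The authors' deposited p-value and false discovery rate columns fit an adjustment over 16014 genes, so the table holds a part of the genes tested, those with a rate under 0.1 in any deposited comparison. Selection on those comparisons makes calls among the treated groups more frequent than in all genes. Each per-library column matched 1 sample. Of 22 symbols turned into dates, 19 were restored through Ensembl identifiers. Coordinates are of whole genes in GENCODE M21 on mm10, found for 10766 genes. The genes given with coordinates are annotated as protein-coding.

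Before the data were examined, a test for counts was planned first, and limma-trend for normalized values. As no counts are in the table, limma 3.58.1 in R 4.3.3 was used on log2(level + 1) with trend and robust empirical Bayes, 1 coefficient per group and all libraries in 1 fit. A filter of level 1 in at least 3 libraries removed 0 genes. Adjusted p-values are Benjamini-Hochberg values over the listed genes of each of 17 comparisons, called under 0.05. Fixed lists (30, of which 1 had no member in the table) were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, over 493 tests. Named genes are up to 5 risen and 5 fallen with the largest change among called genes whose groups do not overlap and whose higher mean is at least 5. List members with the smallest adjusted p and a fixed set of marker genes are named too, and some genes that the rule would name are not reported here. For the difference of 2 effects the overlap condition was not applied, since 4 groups enter it. Chosen after values were seen were Nkx2-5 in B5 over R5, the levels per library, those of Hoxa10 and Hoxd10, and examples that did not pass. In simulated data of 11220 genes on M4 against R4, 66% of 2-fold and 90% of 4-fold changes were recovered, with 6 false calls. B6hr against R6hr gave 52% and 85%, with 5. These rates are for simulated data only. Alternatives were a replicate block, the compared libraries alone, each library left out, pseudocounts of 0.1 and 5, no filter, quantile normalization and other thresholds. Added after seeing the data were array weights (by the gene-by-gene method, since the REML fit stopped before convergence), adjustment over all genes the authors tested, a block within the compared libraries, the authors' deposited test, and the 6 h groups without number 1. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

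Replicate numbers were taken to pair libraries only where every same-numbered pair's deviations from the group means correlated above 0.1. Only B6hr with R6hr met this (0.59, 0.19 and 0.46, against at most 0.15 between different numbers). M7 with B7 did not (0.61, 0.01 and 0.54). Over all groups the mean same-number correlation was -0.016.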

Results

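RNA was sequenced in bulk from 45 cultures of mouse embryonic stem cells (mESCs) taken along a 9-day course toward spinal dorsal interneurons. The libraries formed 15 groups of 3. D0 was the undifferentiated line, and D3 the neuromesodermal progenitor stage reached under basic FGF and the WNT activator CHIR. From day 3 the R groups received 100 nM retinoic acid (RA) alone, and the B groups RA for 24 h and then RA with 10 ng/ml BMP4 for 24 h. The M groups received both factors together for 48 h, so M against B also differs in BMP4 duration and start. R and M were sampled on days 4, 5, 7 and 9, B on days 5, 7 and 9, and R6hr and B6hr on day 4, 6 h into the second 24 h. Values are the deposited normalized levels of 11220 genes, given as mean ± SD over the 3 libraries of a group. Changes are log2 fold changes of level + 1, which understate the change of low genes. The listed levels summed to between 12245725 and 15868724 per library. The labels' protocol states 30000000 reads per sample, but the depth of each library is unknown. Counts in gene lists are followed by those from p-values adjusted over the list alone, marked alone. The camera test of a list was run with a preset correlation and again with an estimated one, whose adjusted p follows the word estimated. Every listed gene had a deposited false discovery rate under 0.1 in at least 1 of 12 comparisons among the treated groups, so no count here covers the whole transcriptome.

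The first comparison asked what changed between undifferentiated mESCs and day 3. Many caudal progenitor genes rose and many pluripotency genes fell. The T gene (mm10 chromosome 17, 8434423 to 8442496), which encodes the mesodermal transcription factor Brachyury, rose from 21.8 ± 35 in D0 to 5413 ± 7958 in D3 (log2 change 8.15, SE 1.04, adjusted p = 5.7e-08). Hoxb1 rose from 8.09 ± 5.49 in D0 to 14909 ± 24885 in D3 (log2 change 8.17, SE 1.10, adjusted p = 1.6e-07). The other leading risen genes were Foxb1 (7.16), Apln (7.13) and Aplnr (7.12), of which Apln and Aplnr encode a ligand and its receptor. The leading fallen genes were Foxd3 (-7.17), Xaf1 (-6.38), Dusp27 (-5.77), Inhbb (-5.75) and Jam2 (-5.72). Among 17 caudal progenitor genes, 15 rose and 0 fell (15 and 0 alone), with camera adjusted p = 5e-06 (estimated 0.59). Examples were Wnt5b (6.78, adjusted p = 3.5e-16) and Axin2 (3.75, adjusted p = 2.4e-14). Among 20 pluripotency genes, 17 fell and 0 rose (18 and 1 alone), with camera adjusted p = 2.6e-06 (estimated 0.63). Members included Prdm14 (-5.24, adjusted p = 5.8e-09), Klf4 (-4.33, adjusted p = 1.1e-08) and Tbx3 (-5.32, adjusted p = 9e-08). Among 13 WNT target genes, 11 rose and 0 fell (11 and 0 alone), with camera adjusted p = 1.4e-05 (estimated 0.47). Tnfrsf19 (4.16, adjusted p = 6.6e-12) rose with Axin2. Among 15 Hox 1 to 5 genes, 15 rose and 0 fell (15 and 0 alone), with camera adjusted p = 1.7e-06 (estimated 0.63). Among 12 Hox 6 to 9 genes, 11 rose and 0 fell (11 and 0 alone), with camera adjusted p = 0.00016 (estimated 0.67). Examples were Hoxa3 (4.75, adjusted p = 6.1e-11), Hoxb4 (4.58, adjusted p = 6.5e-11), Hoxd9 (4.41, adjusted p = 5.4e-11) and Hoxb6 (5.73, adjusted p = 4.5e-09). In limma-trend, 6161 genes passed an adjusted p under 0.05: 3470 rose and 2691 fell. Of these, 1922 and 1255 changed 2-fold or more. With quantile normalization 2981 rose, 3285 fell and the median log2 change of all genes moved by -0.12. Libraries within both groups differed widely. In D3 replicates 1, 2 and 3 the level of T was 14602, 933 and 706, and that of the neuronal tubulin Tubb3 was 273, 5477 and 4967. In D0 Pou5f1, the core pluripotency factor, stood at 3064, 2678 and 22336, and Tubb3 at 6070.5, 8907 and 2171. With the compared libraries alone 4001 genes were called.

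The first 24 h of RA were read from R4 against D3. Several RA-responsive, neural progenitor and somite genes rose, and some caudal progenitor genes fell. Pax6 (mm10 chromosome 2, 105668900 to 105697364), a neural progenitor transcription factor, rose from 24.7 ± 6.57 in D3 to 2418 ± 603 in R4 (log2 change 6.56, SE 0.59, adjusted p = 4.4e-10). Meox1, a somite gene, rose from 32.5 ± 42 in D3 to 6133 ± 4874 in R4 (log2 change 8.04, SE 0.67, adjusted p = 1e-10). Also leading were Foxc2 (6.80), Cer1 (6.40) and Ednrb (5.59). The leading fallen genes were Trim67 (-7.64), Mixl1 (-5.62), Evx1 (-5.33), Wnt3a (-5.22) and Avpr1a (-5.22). Among 17 retinoic acid target genes, 12 rose and 0 fell (13 and 0 alone), with camera adjusted p = 4.5e-07 (estimated 0.52). Among them were Stra8 (4.69, adjusted p = 1.5e-09), Meis1 (4.96, adjusted p = 2.1e-07), Dhrs3 (3.38, adjusted p = 2.9e-05) and Rarb (3.85, adjusted p = 0.00011), the last encoding an RA receptor. Among 16 pan-neural progenitor genes, 11 rose and 2 fell (11 and 2 alone), with camera adjusted p = 5.9e-05 (estimated 0.62). Besides Pax6 these included Sox1 (4.73, adjusted p = 1.2e-07), Irx3 (3.64, adjusted p = 2e-05) and Hes3 (4.72, adjusted p = 8.3e-05). Among 16 paraxial mesoderm genes, 10 rose and 1 fell (10 and 1 alone), with camera adjusted p = 1e-05 (estimated 0.39). Foxc2 (6.80, adjusted p = 1.7e-11), Foxc1 (3.12, adjusted p = 3e-06) and Pax9 (2.80, adjusted p = 1.2e-05) stood with Meox1. Out of 17 caudal progenitor genes, 7 fell and 0 rose (7 and 2 alone), with camera adjusted p = 0.00025 (estimated 0.64). The list mean (log2 level) was 11.61, 9.21 and 9.28 in D3 replicates 1, 2 and 3 and 7.98, 9.49 and 7.47 in R4. Fallen members included Axin2 (-2.61, adjusted p = 8.1e-10), Wnt3a (-5.22, adjusted p = 2e-08), Wnt5b (-3.24, adjusted p = 4.6e-08) and Evx1 (-5.33, adjusted p = 7.9e-08). Among 22 pan-neuronal genes, 9 fell and 1 rose (13 and 1 alone), with camera adjusted p = 0.0015 (estimated 0.88). Gap43 rose (log2 change 2.06, SE 0.26, adjusted p = 2.5e-07), while Snap25 (-3.15, adjusted p = 9.7e-05), Ina (-1.95, adjusted p = 0.00012) and L1cam (-2.67, adjusted p = 0.00024) fell. Snap25 was at 239, 659.9 and 640.3 in D3 replicates 1, 2 and 3, higher in those that also held more Tubb3. The test called 2722 genes with limma-trend at an adjusted p under 0.05, 1312 higher and 1410 lower in R4. Of these, 451 and 675 changed 2-fold or more. Under quantile normalization 1510 rose and 1393 fell. Called members numbered 6 to 17 in the pan-neuronal list without D3 replicates 1, 2 or 3 or R4 replicate 2. Within the compared libraries alone 1046 genes were called, and the call ended for L1cam (adjusted p = 0.069), and called members numbered 3 in the pan-neuronal list.

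M4 against R4 measured 24 h of BMP4 given together with RA from the progenitor stage. Some lateral mesoderm, surface ectoderm and BMP-responsive genes were higher in M4, and several neural genes lower. Hand1 (mm10 chromosome 11, 57828705 to 57832818), a transcription factor of lateral mesoderm and heart, rose from 25 ± 11.5 in R4 to 3562 ± 741 in M4 (log2 change 7.17, SE 0.91, adjusted p = 1.4e-06). Sox1, an early neural gene, fell from 1444 ± 146 in R4 to 73 ± 61.5 in M4 (log2 change -4.59, SE 0.56, adjusted p = 8.4e-07). Other leading risen genes were Rgs5 (4.92), Msx2 (4.90), Trp63 (4.85) and Cilp (4.44). Trp63 encodes an epithelial p53 relative. The leading fallen genes were Uncx (-6.30), Cer1 (-5.73), Rfx4 (-5.71), Hes3 (-5.61) and Sim1 (-4.94). Among 16 surface ectoderm genes, 11 rose and 0 fell (15 and 0 alone), with camera adjusted p = 1.8e-13 (estimated 0.046). Keratins Krt8 (2.01, adjusted p = 3.1e-08) and Krt18 (1.94, adjusted p = 2e-06) and the ligand gene Wnt6 (2.06, adjusted p = 3.1e-08) rose with Trp63. Among 16 lateral mesoderm genes, 8 rose and 1 fell (9 and 1 alone), with camera adjusted p = 1.7e-05 (estimated 0.47). Tbx5 (3.91, adjusted p = 0.00016), Hand2 (4.41, adjusted p = 0.00022) and Foxf1 (2.58, adjusted p = 0.00081) rose too. Among 17 BMP target genes, 10 rose and 0 fell (13 and 2 alone), with camera adjusted p = 3.3e-07 (estimated 0.62). Risen members included Tbx3 (3.97, adjusted p = 0.00015), Id1 (2.15, adjusted p = 0.00016), Bambi (2.56, adjusted p = 0.0002) and Smad6 (2.05, adjusted p = 0.00091). Out of 16 pan-neural progenitor genes, 11 fell and 0 rose (13 and 0 alone), with camera adjusted p = 1.4e-11 (estimated 0.27). Pax6 (-4.79, adjusted p = 9e-07) and Sox2 (-2.31, adjusted p = 2.3e-06) fell with Sox1. Out of 16 paraxial mesoderm genes, 10 fell and 0 rose (11 and 0 alone), with camera adjusted p = 3.7e-07 (estimated 0.3). Besides Uncx these included Pax9 (-3.12, adjusted p = 7.1e-06), Tbx18 (-3.27, adjusted p = 8.6e-05) and Aldh1a2 (-2.43, adjusted p = 0.00038). Among 15 Notch pathway genes, 9 fell and 0 rose (12 and 2 alone), with camera adjusted p = 5e-06 (estimated 0.38). Lfng (-3.06, adjusted p = 1.1e-06), Notch1 (-1.74, adjusted p = 7.3e-05) and Dll1 (-2.31, adjusted p = 0.0011) were among the fallen. Past an adjusted p under 0.05 in limma-trend lay 1586 genes, with 759 risen, 827 fallen, and 349 and 440 of them changed 2-fold or more. With quantile normalization 877 rose and 785 fell. The number of called genes was 876 without M4 replicate 2. Called members numbered 5 in the Notch pathway list without M4 replicate 2. In the compared libraries alone 364 genes were called, and the call ended for Aldh1a2 (adjusted p = 0.05), and called members numbered 6 in the paraxial mesoderm list and 4 in the Notch pathway list.

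B6hr against R6hr was designed to read the first 6 h of BMP4 after 24 h of RA. In the fit of all libraries no BMP target gene was called higher in B6hr, while a fit of the 6 libraries with a replicate block, given below, called 1 higher and 7 lower. Msx2, a BMP-induced homeobox gene, stood at 63.2, 1859.6 and 2917 in R6hr replicates 1, 2 and 3 and at 22, 1172 and 2213 in B6hr. Hand1 stood at 5.05, 206 and 359 and at 7.41, 133 and 259. In both groups replicate 1 was low in these genes, and replicates 2 and 3 were higher. Out of 17 BMP target genes, 0 passed (0 up and 0 down alone). Its median log2 change was -0.33 and camera did not call it (adjusted p = 0.19, estimated 0.95). Its members Msx1 (log2 change -1.94, SE 0.87, adjusted p = 0.22) and Id3 (log2 change -0.70, SE 0.43, adjusted p = 0.37) did not pass in the fit of all libraries. Out of 15 Hox 1 to 5 genes, 0 passed (0 up and 15 down alone), with camera adjusted p = 3.5e-10 (estimated 0.48). Hoxb2 was at 6527 ± 983 in R6hr and 1361 ± 405 in B6hr (log2 change -2.29, SE 0.67, adjusted p = 0.14). Out of 17 retinoic acid target genes, 0 passed (1 up and 14 down alone), with camera adjusted p = 3.3e-07 (estimated 0.52). The RA-degrading enzyme gene Cyp26a1 was at 3247 ± 345 in R6hr and 968 ± 264 in B6hr (log2 change -1.77, SE 0.58, adjusted p = 0.14). Out of 20 pluripotency genes, 0 passed (0 up and 0 down alone), with camera adjusted p = 8.2e-06 (estimated 0.67). Only 2 genes passed an adjusted p under 0.05 in limma-trend, both lower in B6hr. They were Sod3 (log2 change -2.07, SE 0.39, adjusted p = 0.037), encoding extracellular superoxide dismutase, and Slc26a8 (log2 change -1.74, SE 0.32, adjusted p = 0.037). At an unadjusted p under 0.05 there were 2161 genes. Same-numbered libraries deviated together in this pair of groups. A fit of the 6 libraries alone with the replicate number as a block, chosen after seeing the data, called 2902 genes, 1186 higher and 1716 lower in B6hr. With the block over all libraries 2 passed, and with the 6 libraries and no block 847. In the blocked fit of 6 libraries 15 of 15 Hox 1 to 5 genes fell (camera adjusted p = 1.2e-13, estimated 0.67). Of 17 RA target genes 16 fell and 1 rose there (camera adjusted p = 2.3e-11, estimated 0.67). Of 17 BMP target genes 7 fell and 1 rose (camera adjusted p = 0.019, estimated 0.67). Of 20 pluripotency genes 15 rose and 1 fell (camera adjusted p = 1.6e-08, estimated 0.67). Msx1, Id3, Hoxb2 and Cyp26a1 were called lower in that fit (adjusted p = 0.0048, 0.024, 0.009 and 0.01). Fallen too were Hoxb1 (log2 change -2.86, SE 0.31, adjusted p = 0.0088) and Lhx1 (log2 change -2.30, SE 0.14, adjusted p = 6.0e-04), and risen Foxd3 (log2 change 2.39, SE 0.35, adjusted p = 0.0021) and Nanog (log2 change 1.86, SE 0.24, adjusted p = 0.0013). The number of called genes was 1 without B6hr replicate 1, 0 without B6hr replicate 2, 10 without B6hr replicate 3, 0 without R6hr replicate 1 and 0 without R6hr replicate 2. Leaving out 1 library ended the call of Slc26a8 without B6hr replicates 1 or 2 or R6hr replicates 1, 2 or 3 (adjusted p = 0.068 to 0.25) and Sod3 without B6hr replicates 2 or 3 or R6hr replicates 1 or 2 (0.097 to 0.26). With the compared libraries alone 847 genes were called, and called members numbered 1 in the BMP target list, 14 in the Hox 1 to 5 list, 15 in the retinoic acid target list and 6 in the pluripotency list. The call also ended for Sod3 (adjusted p = 0.051) and Slc26a8 (0.051) with a pseudocount of 0.1; Sod3 (0.13) with quantile normalization; and Sod3 (0.053) and Slc26a8 (0.053) with adjustment over all genes the authors tested. Past 0.05 (adjusted p) came Hoxb2 (0.0082) with the compared libraries alone and Cyp26a1 (0.011) with the compared libraries alone. Called list members numbered 2 in the Hox 1 to 5 list with the authors' deposited test.

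B5 against R5 measured 24 h of BMP4 given after 24 h of RA. Some BMP-responsive and lateral mesoderm genes were higher in B5, and some neural genes lower. Hand1 rose from 15.1 ± 6.45 in R5 to 1039 ± 221 in B5 (log2 change 6.07, SE 0.91, adjusted p = 0.00011). Pax2 (mm10 chromosome 19, 44756045 to 44837871), a gene of inhibitory dorsal interneurons, fell from 705 ± 212 in R5 to 68.8 ± 33.8 in B5 (log2 change -3.41, SE 0.55, adjusted p = 0.00024). Further leading risen genes were Rgs5 (5.33), Foxd3 (4.87), Zfp804a (4.17) and Grin2c (4.00), including Foxd3, a neural crest and dI2 interneuron gene. The fallen genes were led by Dbx1 (-5.20), Vit (-3.67), Sostdc1 (-3.14) and Slco1a5 (-2.90). Of 17 BMP target genes, 5 rose and 0 fell (9 and 1 alone), with camera adjusted p = 0.00016 (estimated 0.7). They included Bambi (2.28, adjusted p = 0.0023), Smad9 (3.71, adjusted p = 0.0049) and Id1 (1.36, adjusted p = 0.027). Out of 16 lateral mesoderm genes, 5 rose and 1 fell (8 and 1 alone), with camera adjusted p = 0.00016 (estimated 0.52). Tbx5 (3.53, adjusted p = 0.0017), Tbx20 (2.84, adjusted p = 0.0053) and Gata5 (3.80, adjusted p = 0.0071) rose, and Nkx2-5 (-0.90, adjusted p = 0.033) fell. Among 13 endothelial and blood genes, 3 rose and 0 fell (4 and 0 alone), with camera adjusted p = 5.9e-05 (estimated 0.27). Receptor gene Tek (1.47, adjusted p = 0.0017) and Lyl1 (1.94, adjusted p = 0.0053) were risen members. Of 16 pan-neural progenitor genes, 4 fell and 0 rose (11 and 0 alone), with camera adjusted p = 5.2e-07 (estimated 0.47). Sox3 (-2.07, adjusted p = 0.008) and Nes (-1.13, adjusted p = 0.011) fell, while Irx3 (log2 change -1.89, SE 0.59, adjusted p = 0.051) did not pass. Among 20 dI4 to dI6 interneuron genes, 4 fell and 0 rose (5 and 0 alone), with camera adjusted p = 0.0051 (estimated 0.67). Besides Pax2 these included Prdm12 (-2.65, adjusted p = 0.03), Dmrt3 (-1.73, adjusted p = 0.038) and Gbx1 (-1.31, adjusted p = 0.047). Of 15 Hox 1 to 5 genes, 3 fell and 0 rose (9 and 0 alone), with camera adjusted p = 6.6e-06 (estimated 0.63). Hoxb4 (-1.49, adjusted p = 0.029) and Hoxd4 (-2.06, adjusted p = 0.033) fell. In limma-trend, 672 genes passed an adjusted p under 0.05: 310 rose and 362 fell. Of these, 153 and 165 changed 2-fold or more. With quantile normalization 398 rose and 339 fell. The number of called genes was 341 without B5 replicate 1, 196 without B5 replicate 2, 336 without R5 replicate 2 and 222 without R5 replicate 3. Called members numbered 2 in the BMP target list without B5 replicates 1 or 2 or R5 replicates 1, 2 or 3, 0 to 7 in the pan-neural progenitor list without B5 replicates 1, 2 or 3 or R5 replicates 2 or 3, 1 to 2 in the dI4 to dI6 interneuron list without B5 replicates 1 or 2 or R5 replicates 2 or 3 and 0 to 5 in the Hox 1 to 5 list without B5 replicates 1, 2 or 3 or R5 replicates 2 or 3. Without 1 library the call ended for Id1 without B5 replicates 1 or 2 or R5 replicates 1, 2 or 3 (adjusted p = 0.059 to 0.11), Nkx2-5 without B5 replicates 1, 2 or 3 or R5 replicates 1 or 2 (0.058 to 0.12) and Prdm12 without B5 replicates 1 or 2 or R5 replicates 2 or 3 (0.053 to 0.17). Calls also ended for Dmrt3 without B5 replicates 1, 2 or 3 or R5 replicates 1, 2 or 3 (adjusted p = 0.063 to 0.12), Gbx1 without B5 replicates 1 or 2 or R5 replicates 1 or 3 (0.12 to 0.2) and Hoxb4 without B5 replicates 1 or 2 or R5 replicates 2 or 3 (0.066 to 0.2). A left-out library likewise ended the call of Hoxd4 without B5 replicates 1 or 2 or R5 replicates 2 or 3 (adjusted p = 0.057 to 0.24), Sostdc1 without B5 replicates 2 or 3 or R5 replicates 2 or 3 (0.06 to 0.28) and Sox3 without B5 replicate 2 or R5 replicate 3 (0.06 to 0.063). Further calls lost were Nes without B5 replicate 2 or R5 replicates 2 or 3 (adjusted p = 0.051 to 0.1). Irx3 passed without B5 replicate 3 (adjusted p = 0.011). Within the compared libraries alone 97 genes were called, and the call ended for Foxd3 (adjusted p = 0.069), Grin2c (0.069), Vit (0.063), Sostdc1 (0.19), Nkx2-5 (0.18), Tek (0.08), Lyl1 (0.12), Nes (0.063), Gbx1 (0.13), Hoxb4 (0.098) and Hoxd4 (0.15), and called members numbered 0 in the endothelium and blood list, 2 in the pan-neural progenitor list and 0 in the Hox 1 to 5 list. The call also ended for Gbx1 (adjusted p = 0.054) with a pseudocount of 0.1; Sostdc1 (0.054) with a pseudocount of 5; Nkx2-5 (0.077) and Gbx1 (0.1) with quantile normalization; and Sostdc1 (0.05), Dmrt3 (0.054) and Gbx1 (0.067) with adjustment over all genes the authors tested. Past 0.05 (adjusted p) came Irx3 (0.048) with a pseudocount of 5 and Irx3 (0.049) with the authors' deposited test. Called list members numbered 2 in the pan-neural progenitor list and 2 in the dI4 to dI6 interneuron list with adjustment over all genes the authors tested; and 8 in the pan-neural progenitor list with the authors' deposited test.

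After 48 h of combined treatment, M5 against R5 showed a broad change. Many lateral mesoderm, endothelial and pluripotency genes were higher in M5, and many neural progenitor genes lower. Tbx20 (mm10 chromosome 9, 24718138 to 24774303), a heart transcription factor, rose from 17.3 ± 4.18 in R5 to 1337 ± 311 in M5 (log2 change 6.19, SE 0.63, adjusted p = 2.6e-09). Pax6 fell from 4917 ± 1625 in R5 to 164 ± 120.1 in M5 (log2 change -5.08, SE 0.59, adjusted p = 3.2e-08). The leading risen genes also included Hand1 (8.54), Tac2 (6.81), Mab21l2 (6.14) and Rgs5 (6.13), and the fallen genes Dbx1 (-8.41), Fam181a (-7.17), Cp (-7.14), Hes5 (-6.87) and Hes3 (-6.58). Dbx1, a gene of intermediate spinal progenitors, was at 4136 ± 2859 in R5 and 14.7 ± 17.1 in M5. Of 16 lateral mesoderm genes, 11 rose and 1 fell (12 and 1 alone), with camera adjusted p = 0.00016 (estimated 0.52). Tbx5 (5.06, adjusted p = 5.2e-07) and Gata6 (3.69, adjusted p = 1e-05) rose with Hand1. Out of 13 endothelial and blood genes, 11 rose and 0 fell (11 and 0 alone), with camera adjusted p = 3.1e-05 (estimated 0.24). Tek (2.67, adjusted p = 6.8e-09), Lyl1 (3.94, adjusted p = 9.9e-09) and Pecam1 (3.38, adjusted p = 4.1e-06) rose. Of 20 pluripotency genes, 16 rose and 0 fell (17 and 0 alone), with camera adjusted p = 0.00021 (estimated 0.75). Among 16 pan-neural progenitor genes, 16 fell and 0 rose (16 and 0 alone), with camera adjusted p = 6e-10 (estimated 0.37). These included Sox1 (-5.03, adjusted p = 1.6e-08), Sox3 (-4.29, adjusted p = 1.6e-08), Nes (-2.43, adjusted p = 1.7e-08) and Sox2 (-2.65, adjusted p = 2.4e-08). Among 15 roof plate genes, 11 fell and 0 rose (11 and 0 alone), with camera adjusted p = 0.0022 (estimated 0.75). Wnt3a (-3.98, adjusted p = 1.1e-06), Bmp7 (-1.96, adjusted p = 1.9e-06) and Zic1 (-5.14, adjusted p = 5.9e-06) fell. Among 18 dorsal neural progenitor genes, 11 fell and 0 rose (11 and 0 alone), with camera adjusted p = 0.00022 (estimated 0.63). Zic2 (-3.13, adjusted p = 3.7e-08) and Pax7 (-4.96, adjusted p = 4.4e-08) fell. The test called 4975 genes with limma-trend at an adjusted p under 0.05, 2361 higher and 2614 lower in M5. Of these, 1125 and 1266 changed 2-fold or more. Under quantile normalization 2696 rose and 2195 fell. Called members numbered 8 to 9 in the pluripotency list without M5 replicate 1 or R5 replicate 3.

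M5 against B5 compared combined (48 h of BMP4) with sequential treatment (24 h) at day 5. Several surface ectoderm and some lateral mesoderm genes were higher in M5, and several dorsal neural genes lower. Pax3 (mm10 chromosome 1, 78101267 to 78197134), a dorsal neural tube gene, was lower in M5, at 3942 ± 3157 in B5 and 200.4 ± 254 in M5 (log2 change -4.84, SE 0.89, adjusted p = 0.00021). Tbx20 was higher in M5, at 135 ± 51.4 in B5 and 1337 ± 311 in M5 (log2 change 3.35, SE 0.63, adjusted p = 0.00027). The largest rises were in Tac2 (5.04), Mab21l2 (4.92), Nr1h5 (4.26), Crhbp (3.67) and Fitm1 (3.66), and the largest falls, besides Pax3, in Cp (-5.87), Hes5 (-5.44), Prdm13 (-4.97) and Hes3 (-4.91). Out of 16 surface ectoderm genes, 8 rose and 1 fell (11 and 1 alone), with camera adjusted p = 7.2e-06 (estimated 0.39). Krt8 (1.27, adjusted p = 2.8e-05), Grhl3 (1.74, adjusted p = 0.00013) and Krt5 (2.14, adjusted p = 0.00033) rose. Among 16 lateral mesoderm genes, 4 rose and 0 fell (6 and 0 alone), with camera adjusted p = 0.0025 (estimated 0.63). Gata6 (2.10, adjusted p = 0.014) and Gata4 (1.92, adjusted p = 0.019) rose, and Hand1 (log2 change 2.47, SE 0.91, adjusted p = 0.055) did not pass. Out of 16 pan-neural progenitor genes, 12 fell and 0 rose (13 and 0 alone), with camera adjusted p = 9.2e-10 (estimated 0.37). Sox2 (-2.21, adjusted p = 3.9e-06), Rfx4 (-4.64, adjusted p = 3.5e-05) and Sox1 (-3.42, adjusted p = 4.9e-05) fell. Out of 18 dorsal neural progenitor genes, 10 fell and 0 rose (13 and 0 alone), with camera adjusted p = 2.2e-08 (estimated 0.47). Zic2 (-3.49, adjusted p = 4.7e-08), Zic5 (-3.53, adjusted p = 5e-07) and Zic1 (-4.62, adjusted p = 0.00012) fell. Among 13 p53 target genes, 8 fell and 0 rose (8 and 0 alone), with camera adjusted p = 3.3e-07 (estimated 0.38). Zmat3 (-0.73, adjusted p = 7.5e-07), Cdkn1a (-0.89, adjusted p = 2.7e-06) and Ccng1 (-0.66, adjusted p = 9.9e-06) fell, Cdkn1a encoding the cell cycle inhibitor p21. Past an adjusted p under 0.05 in limma-trend lay 1997 genes, with 961 risen, 1036 fallen, and 460 and 512 of them changed 2-fold or more. With quantile normalization 1022 rose and 994 fell. The number of called genes was 1026 without B5 replicate 3, 1225 without M5 replicate 1 and 1142 without M5 replicate 2. Called members numbered 1 to 2 in the lateral mesoderm list without B5 replicates 2 or 3 or M5 replicate 2. Leaving out 1 library ended the call of Gata4 without B5 replicates 2 or 3 or M5 replicates 1 or 2 (adjusted p = 0.054 to 0.098) and Gata6 without B5 replicate 3 or M5 replicate 2 (0.054 to 0.087). With the compared libraries alone 1020 genes were called. Past 0.05 (adjusted p) came Hand1 (0.0029) with the compared libraries alone, Hand1 (0.028) with a pseudocount of 5, Hand1 (0.04) with quantile normalization and Hand1 (0.0042) with the authors' deposited test.

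**Figure D1:**
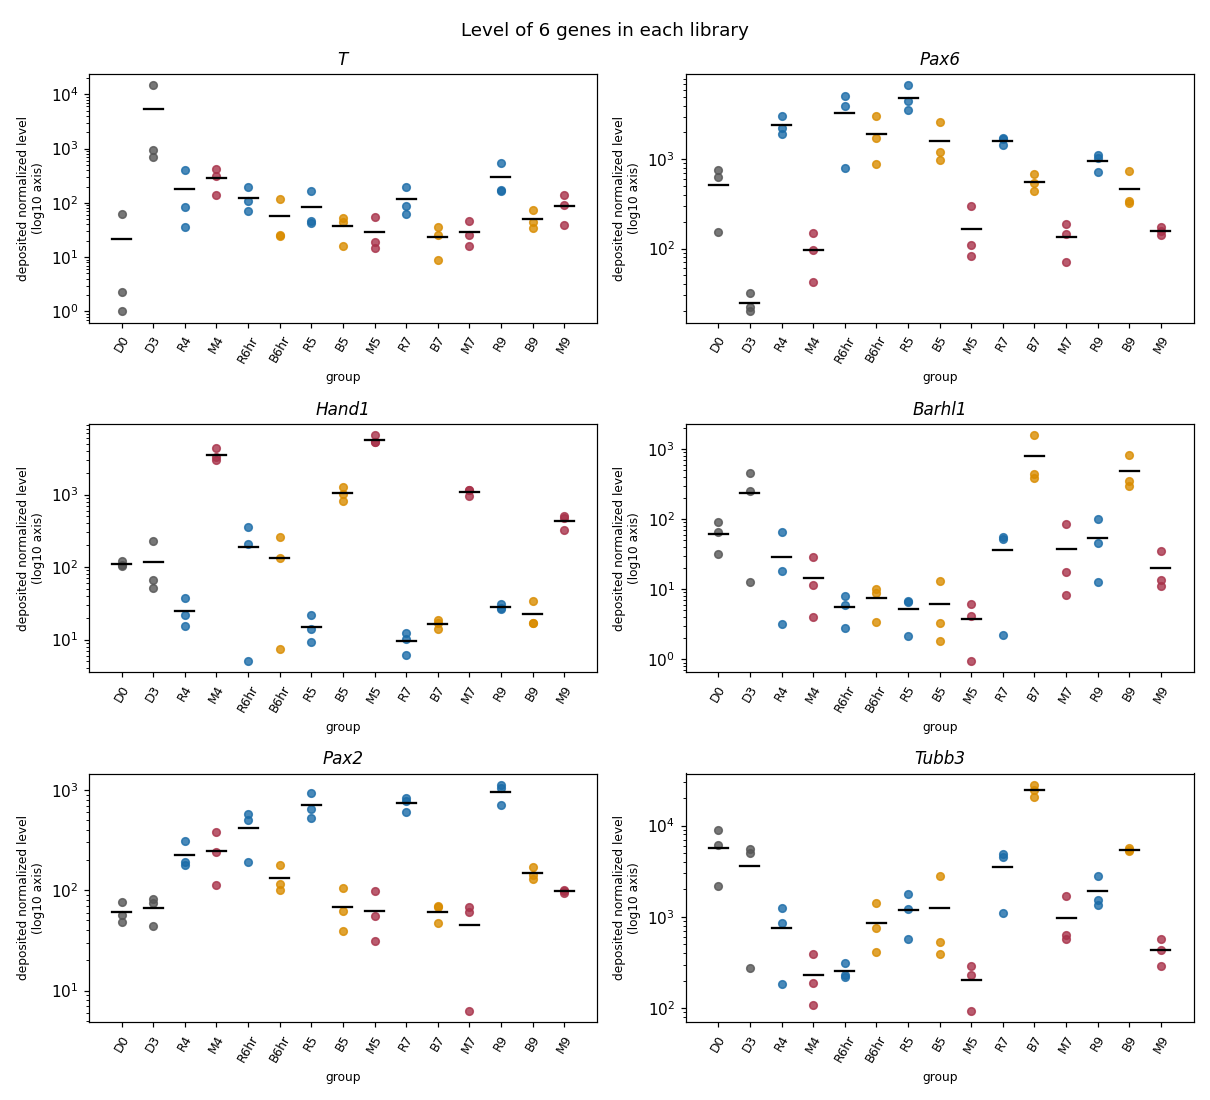
Deposited normalized level (log10 axis) of 6 genes in each library, by group. Points are single libraries and short bars group means. Hand1 averages 5715 in M5 and 15.1 in R5, and Barhl1 802 in B7 and 36.5 in R7, while T is spread widely within D3.

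At day 7, B7 against R7 asked which interneuron classes followed sequential BMP4. Several genes of the dI1 to dI3 interneurons, the dorsalmost sensory classes, and some pluripotency genes were higher in B7, and several dI4 to dI6 genes lower. Barhl1 (mm10 chromosome 2, 28907679 to 28916668), a dI1 gene, rose from 36.5 ± 29.7 in R7 to 802 ± 673 in B7 (log2 change 4.93, SE 1.12, adjusted p = 0.0024). Pax2 fell from 739 ± 123 in R7 to 61.2 ± 12.3 in B7 (log2 change -3.58, SE 0.55, adjusted p = 3e-05). Leading risen genes were Upk1b (5.34), Kcnmb2 (5.28), Lhx9 (5.24), Dbh (5.21) and Upk3b (5.13). Dbh encodes the enzyme that makes noradrenaline. Leading fallen genes were Dbx1 (-5.21), Sp8 (-3.95), Hoxaas3 (-3.92), Sim1 (-3.79) and Slco1a5 (-3.77). Among 14 dI1 to dI3 interneuron genes, 10 rose and 0 fell (10 and 0 alone), with camera adjusted p = 5e-06 (estimated 0.63). Beside Barhl1 stood Lhx9 (5.24, adjusted p = 3.8e-05), Foxd3 (4.86, adjusted p = 0.00014), Barhl2 (5.09, adjusted p = 0.00095) and Isl1 (3.65, adjusted p = 0.0013), Isl1 being a dI3 gene. Foxd3 is also a gene of undifferentiated cells, at 2670.5 ± 697 in D0. Among 20 pluripotency genes, 4 rose and 0 fell (16 and 1 alone), with camera adjusted p = 0.00014 (estimated 0.75). Out of 20 dI4 to dI6 interneuron genes, 7 fell and 2 rose (10 and 3 alone), with camera adjusted p = 0.011 (estimated 0.72). Pax8 (-2.05, adjusted p = 0.0034), Gbx1 (-1.60, adjusted p = 0.0054) and Lbx1 (-2.34, adjusted p = 0.0071) fell, while Wt1 (2.36, adjusted p = 0.00046) rose. Wt1 also marks mesothelium, as do the leading genes Upk1b and Upk3b. Out of 22 pan-neuronal genes, 5 rose and 0 fell (7 and 0 alone), with camera adjusted p = 0.00025 (estimated 0.8). Tubb3 rose from 3513 ± 2106 in R7 to 24499.6 ± 3596 in B7 (log2 change 3.07, SE 0.85, adjusted p = 0.0099), with Stmn2 (2.22, adjusted p = 0.0013) and L1cam (2.02, adjusted p = 0.0063). The list mean (log2 level) was 9.68, 9.88 and 7.91 in R7 replicates 1, 2 and 3 and 10.20, 10.34 and 10.81 in B7. Among 17 neural crest genes, 5 rose and 1 fell (5 and 1 alone). Its median log2 change was -0.02 and camera did not call it (adjusted p = 0.23, estimated 0.95). Erbb3 (2.11, adjusted p = 9.4e-08) and Sox10 (2.64, adjusted p = 0.017) rose. Among 12 muscle genes, 6 fell and 0 rose (10 and 0 alone), with camera adjusted p = 5.3e-06 (estimated 0.48). Actc1 (-3.02, adjusted p = 1.8e-05), Myl1 (-3.45, adjusted p = 3.3e-05) and Tnni1 (-3.00, adjusted p = 0.00014) fell. In limma-trend, 2661 genes passed an adjusted p under 0.05: 1360 rose and 1301 fell. Of these, 746 and 430 changed 2-fold or more. Under quantile normalization 1282 rose and 1339 fell. The number of called genes was 1441 without B7 replicate 1 and 1766 without R7 replicate 3. Called members numbered 0 to 12 in the pluripotency list without B7 replicates 1 or 3 or R7 replicate 1 and 1 to 3 in the pan-neuronal list without B7 replicates 1, 2 or 3 or R7 replicate 3. Without 1 library the call ended for Tubb3 without R7 replicate 3 (adjusted p = 0.073), L1cam without R7 replicate 3 (0.055) and Sox10 without R7 replicate 3 (0.15). Within the compared libraries alone 1475 genes were called, and the call ended for Sox10 (adjusted p = 0.062), and called members numbered 2 in the pluripotency list. Called list members numbered 9 in the pan-neuronal list and 10 in the muscle list with quantile normalization; and 10 in the pluripotency list with the authors' deposited test.

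M7 against R7 compared combined treatment with RA alone at day 7. Many lateral mesoderm and endothelial genes and embryonic globin genes were higher in M7, and many dorsal progenitor genes lower. Gata5 (mm10 chromosome 2, 180325133 to 180334699), a mesoderm and endoderm transcription factor, rose from 9.59 ± 1.28 in R7 to 1159.5 ± 507 in M7 (log2 change 6.66, SE 0.87, adjusted p = 2.2e-07). Pax7, a dorsal progenitor gene, fell from 1217 ± 135 in R7 to 66.7 ± 58.8 in M7 (log2 change -4.58, SE 0.59, adjusted p = 1.6e-07). Leading risen genes besides Gata5 were Hlx (7.38), Hand1 (6.73), Hba-x (6.72) and Tac2 (6.49), and leading fallen genes Cp (-6.79), Dbx1 (-6.63), Gsx1 (-5.90), Myh3 (-5.80) and Sox21 (-5.28). Out of 16 lateral mesoderm genes, 11 rose and 0 fell (12 and 1 alone), with camera adjusted p = 1.3e-05 (estimated 0.47). Foxf1 (4.91, adjusted p = 5.2e-09), Tbx20 (5.07, adjusted p = 9.1e-08) and Wt1 (3.58, adjusted p = 1.2e-07) rose. Of 13 endothelial and blood genes, 12 rose and 0 fell (12 and 0 alone), with camera adjusted p = 2.1e-05 (estimated 0.24). Sox18 (2.67, adjusted p = 8.1e-07), Tie1 (3.05, adjusted p = 3.3e-06) and Hbb-y (5.24, adjusted p = 8.2e-06) rose. The embryonic globin gene Hba-x stood at 418, 1559 and 51.7 in M7 replicates 1, 2 and 3, and reads of similar globin genes may have been split in counting. Of 18 dorsal neural progenitor genes, 15 fell and 0 rose (16 and 0 alone), with camera adjusted p = 1.7e-06 (estimated 0.52). Zic2 (-3.29, adjusted p = 1.3e-08) and Zic5 (-3.49, adjusted p = 7.1e-08) fell. Among 7 Hox 10 to 13 genes, 6 rose and 0 fell (6 and 0 alone), with camera adjusted p = 0.022 (estimated 0.37). Hoxa10 (2.77, adjusted p = 0.00019) and Hoxd10 (2.49, adjusted p = 0.00022) rose, at levels of 185 ± 59.7 and 12.4 ± 5.70 in M7. The test called 4882 genes with limma-trend at an adjusted p under 0.05, 2571 higher and 2311 lower in M7. Of these, 1371 and 1077 changed 2-fold or more. In the compared libraries alone 3238 genes were called.

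Combined against sequential treatment at day 7, M7 against B7, set many neuronal genes against many lateral mesoderm genes. Tubb3 (mm10 chromosome 8, 123411424 to 123422015) was lower in M7, at 24499.6 ± 3596 in B7 and 968 ± 636 in M7 (log2 change -4.84, SE 0.85, adjusted p = 3.6e-05). Foxf1, a lateral plate gene, was higher in M7, at 21 ± 9.46 in B7 and 685 ± 348 in M7 (log2 change 4.90, SE 0.52, adjusted p = 1.1e-08). Leading risen genes besides Foxf1 were Hand1 (5.96), Hba-x (5.22), Gata5 (4.89) and Nr1h5 (4.85), and leading fallen genes besides Tubb3 Grm2 (-5.11), Foxd3 (-4.97), Gsx1 (-4.93) and Barhl1 (-4.72). Of 22 pan-neuronal genes, 21 fell and 0 rose (21 and 0 alone), with camera adjusted p = 6.3e-11 (estimated 0.56). Elavl2 (-1.99, adjusted p = 8.7e-09), Ina (-3.22, adjusted p = 2.5e-08) and Stmn2 (-3.63, adjusted p = 3.2e-07) fell. Out of 14 dI1 to dI3 interneuron genes, 9 fell and 1 rose (10 and 1 alone), with camera adjusted p = 0.00037 (estimated 0.7). Pou4f1 (-3.30, adjusted p = 8.2e-07), Tlx3 (-4.51, adjusted p = 1.6e-05) and Pou4f2 (-3.39, adjusted p = 0.00057) fell, Tlx3 being a dI3 and dI5 gene. Of 16 lateral mesoderm genes, 13 rose and 0 fell (13 and 0 alone), with camera adjusted p = 3.8e-05 (estimated 0.48). Tbx20 (4.39, adjusted p = 1.7e-06) rose with Foxf1. Among 14 hypoxia and glycolysis genes, 7 fell and 0 rose (9 and 0 alone), with camera adjusted p = 0.0036 (estimated 0.63). Ankrd37 (-1.24, adjusted p = 0.00036), Egln3 (-1.08, adjusted p = 0.00073) and Pdk1 (-1.19, adjusted p = 0.0016) fell. Past an adjusted p under 0.05 in limma-trend lay 4673 genes, with 2437 risen, 2236 fallen, and 971 and 1102 of them changed 2-fold or more.

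At day 9, B9 against R9 repeated the sequential comparison. Some dI1 to dI3 and neural crest genes were higher in B9, and Pax2 and some other dI4 to dI6 genes lower. Barhl2 rose from 49.9 ± 33.6 in R9 to 516 ± 98.2 in B9 (log2 change 3.57, SE 1.04, adjusted p = 0.023). Pax2 fell from 961 ± 221 in R9 to 148 ± 20.1 in B9 (log2 change -2.67, SE 0.55, adjusted p = 0.0018). Leading risen genes were Upk1b (5.76), Upk3b (5.28), Dbh (4.21), Pdyn (4.11) and Tgm7 (4.03), Pdyn encoding the opioid precursor prodynorphin. Leading fallen genes were Sost (-3.27), Rspo2 (-3.15), Slc6a11 (-2.98), Dbx1 (-2.98) and Hoxd1 (-2.85). Of 14 dI1 to dI3 interneuron genes, 5 rose and 0 fell (6 and 0 alone), with camera adjusted p = 0.00054 (estimated 0.72). Foxd3 (2.88, adjusted p = 0.023), Lhx9 (2.69, adjusted p = 0.028), Isl1 (2.50, adjusted p = 0.03) and Barhl1 (3.46, adjusted p = 0.039) rose. Of 20 dI4 to dI6 interneuron genes, 7 fell and 1 rose (9 and 2 alone), with camera adjusted p = 0.0067 (estimated 0.68). Gbx1 (-1.81, adjusted p = 0.004) and Lmx1b (-1.77, adjusted p = 0.0059) fell, and Wt1 (3.13, adjusted p = 3e-05) rose. Out of 17 neural crest genes, 6 rose and 1 fell (6 and 1 alone), with camera adjusted p = 0.044 (estimated 0.88). Erbb3 (1.22, adjusted p = 0.0005) and Sox10 (3.04, adjusted p = 0.012) rose, both Schwann cell genes too, and Sox8 (-0.73, adjusted p = 0.0083) fell. Among 22 pan-neuronal genes, 0 passed (0 up and 0 down alone), with camera adjusted p = 0.026 (estimated 0.92). Tubb3 was at 1899 ± 791 in R9 and 5461 ± 213 in B9 (log2 change 1.60, SE 0.85, adjusted p = 0.22). In limma-trend, 1328 genes passed an adjusted p under 0.05: 687 rose and 641 fell. Of these, 358 and 202 changed 2-fold or more. The number of called genes was 721 without B9 replicate 1, 770 without B9 replicate 3, 556 without R9 replicate 2 and 707 without R9 replicate 3. Called members numbered 0 to 1 in the dI1 to dI3 interneuron list without B9 replicates 1, 2 or 3 or R9 replicates 2 or 3, 4 to 5 in the dI4 to dI6 interneuron list without B9 replicates 1, 2 or 3 or R9 replicates 1, 2 or 3 and 4 in the neural crest list without B9 replicates 1 or 3 or R9 replicate 3. Without 1 library the call ended for Barhl2 without B9 replicates 1, 2 or 3 or R9 replicates 2 or 3 (adjusted p = 0.051 to 0.11), Lhx9 without B9 replicates 1, 2 or 3 or R9 replicates 2 or 3 (0.054 to 0.13) and Isl1 without B9 replicates 1 or 2 or R9 replicates 1, 2 or 3 (0.052 to 0.13). Calls also ended for Barhl1 without B9 replicates 1, 2 or 3 or R9 replicates 2 or 3 (adjusted p = 0.067 to 0.19), Sox10 without B9 replicate 1 or R9 replicate 3 (0.063 to 0.066) and Dbx1 without B9 replicates 2 or 3 or R9 replicates 1, 2 or 3 (0.068 to 0.13). A left-out library likewise ended the call of Foxd3 without B9 replicates 2 or 3 or R9 replicates 2 or 3 (adjusted p = 0.068 to 0.11) and Sox8 without B9 replicate 3 (0.054). Within the compared libraries alone the call ended for Sox8 (adjusted p = 0.062), and called members numbered 7 in the pan-neuronal list. The call also ended for Dbx1 (adjusted p = 0.051) and Barhl1 (0.055) with a pseudocount of 0.1; Dbx1 (0.052) and Barhl1 (0.056) with adjustment over all genes the authors tested; and Sox8 (0.059) with the authors' deposited test. Past 0.05 (adjusted p) came Tubb3 (0.011) with the compared libraries alone. Called list members numbered 1 in the pan-neuronal list with quantile normalization; and 5 in the dI4 to dI6 interneuron list with adjustment over all genes the authors tested.

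M9 against R9 compared combined treatment with RA alone at day 9. Many lateral mesoderm genes were higher in M9, and several dorsal interneuron, glial and pluripotency genes lower. Hand2 (mm10 chromosome 8, 57320983 to 57324633) rose from 19.7 ± 9.07 in R9 to 1476 ± 607 in M9 (log2 change 6.19, SE 0.80, adjusted p = 1.8e-07). Lbx1, a dI4 to dI6 gene, fell from 251 ± 55.2 in R9 to 16.9 ± 0.57 in M9 (log2 change -3.79, SE 0.61, adjusted p = 7.2e-06). Leading risen genes besides Hand2 were Gata5 (6.07), Angptl7 (5.89), Hlx (5.76) and Bnc1 (5.72), and leading fallen genes Cp (-6.04), Gsx1 (-5.11), Dbx1 (-4.92), Fos (-4.77) and Acsbg1 (-4.29). Among 16 lateral mesoderm genes, 10 rose and 1 fell (11 and 1 alone), with camera adjusted p = 0.0022 (estimated 0.63). Wt1 (3.92, adjusted p = 2.4e-08), Tbx20 (5.15, adjusted p = 6.7e-08) and Foxf1 (4.08, adjusted p = 1.6e-07) rose. Among 20 dI4 to dI6 interneuron genes, 14 fell and 1 rose (14 and 1 alone), with camera adjusted p = 3.7e-05 (estimated 0.52). Pax8 (-3.68, adjusted p = 2.6e-07) and Slc6a5 (-3.69, adjusted p = 1.3e-06) fell, Slc6a5 encoding the glycine transporter GlyT2. Among 14 glial genes, 7 fell and 1 rose (7 and 1 alone), with camera adjusted p = 0.041 (estimated 0.63). Hopx (-3.98, adjusted p = 1.5e-08), Bcan (-2.44, adjusted p = 1e-05) and Aldh1l1 (-1.31, adjusted p = 0.00075) fell. Out of 20 pluripotency genes, 16 fell and 0 rose (16 and 0 alone), with camera adjusted p = 9.5e-05 (estimated 0.75). Esrrb (-3.38, adjusted p = 1.5e-05) and Dppa5a (-3.06, adjusted p = 6.1e-05) fell. The test called 5726 genes with limma-trend at an adjusted p under 0.05, 3084 higher and 2642 lower in M9. Of these, 1206 and 1361 changed 2-fold or more. Under quantile normalization 2783 rose and 2822 fell. Called members numbered 5 in the glial list without M9 replicate 2.

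M9 against B9 compared combined with sequential treatment at day 9. Many neuronal and pluripotency, several dI1 to dI3 and some immediate early genes were lower in M9, and several cell cycle genes higher. Foxd3 was lower in M9, at 418 ± 111 in B9 and 17 ± 9.39 in M9 (log2 change -4.63, SE 0.84, adjusted p = 5e-05). Mki67 (mm10 chromosome 7, 135689784 to 135716361), a proliferation marker, was higher in M9, at 6551 ± 2298 in B9 and 10511 ± 1993 in M9 (log2 change 0.72, SE 0.17, adjusted p = 0.0011). Leading risen genes were Tbx20 (5.08), Gata5 (4.67), Hand1 (4.27), Dlx5 (4.15) and Frem1 (3.97), and leading fallen genes besides Foxd3 Fos (-4.90), Barhl1 (-4.57), Egr1 (-4.35) and Gsx1 (-4.34). Out of 22 pan-neuronal genes, 16 fell and 0 rose (16 and 0 alone), with camera adjusted p = 3e-06 (estimated 0.67). Ina (-2.33, adjusted p = 5.8e-06), Elavl2 (-1.33, adjusted p = 7.6e-06) and Stmn2 (-2.47, adjusted p = 8.6e-05) fell. Among 14 dI1 to dI3 interneuron genes, 11 fell and 0 rose (11 and 0 alone), with camera adjusted p = 0.0012 (estimated 0.75). Pou4f2 (-4.06, adjusted p = 6.4e-05) and Tlx3 (-3.43, adjusted p = 0.00042) fell. Of 20 pluripotency genes, 18 fell and 0 rose (18 and 0 alone), with camera adjusted p = 1.3e-05 (estimated 0.67). Foxd3 is high in undifferentiated cells too (2670.5 in D0). Among 13 cell cycle genes, 13 rose and 0 fell (13 and 0 alone), with camera adjusted p = 0.00087 (estimated 0.75). Tyms (1.11, adjusted p = 9e-07), Rrm2 (0.72, adjusted p = 0.0013) and Cdk1 (0.52, adjusted p = 0.0018) rose. Among 12 immediate early genes, 6 fell and 0 rose (6 and 0 alone), with camera adjusted p = 0.0017 (estimated 0.48). Ier2 (-1.31, adjusted p = 2.1e-08), Junb (-3.07, adjusted p = 4.5e-07) and Dusp1 (-1.18, adjusted p = 6.8e-06) fell with Fos and Egr1. Past an adjusted p under 0.05 in limma-trend lay 5777 genes, with 3114 risen, 2663 fallen, and 854 and 1366 of them changed 2-fold or more.

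**Figure D2:**
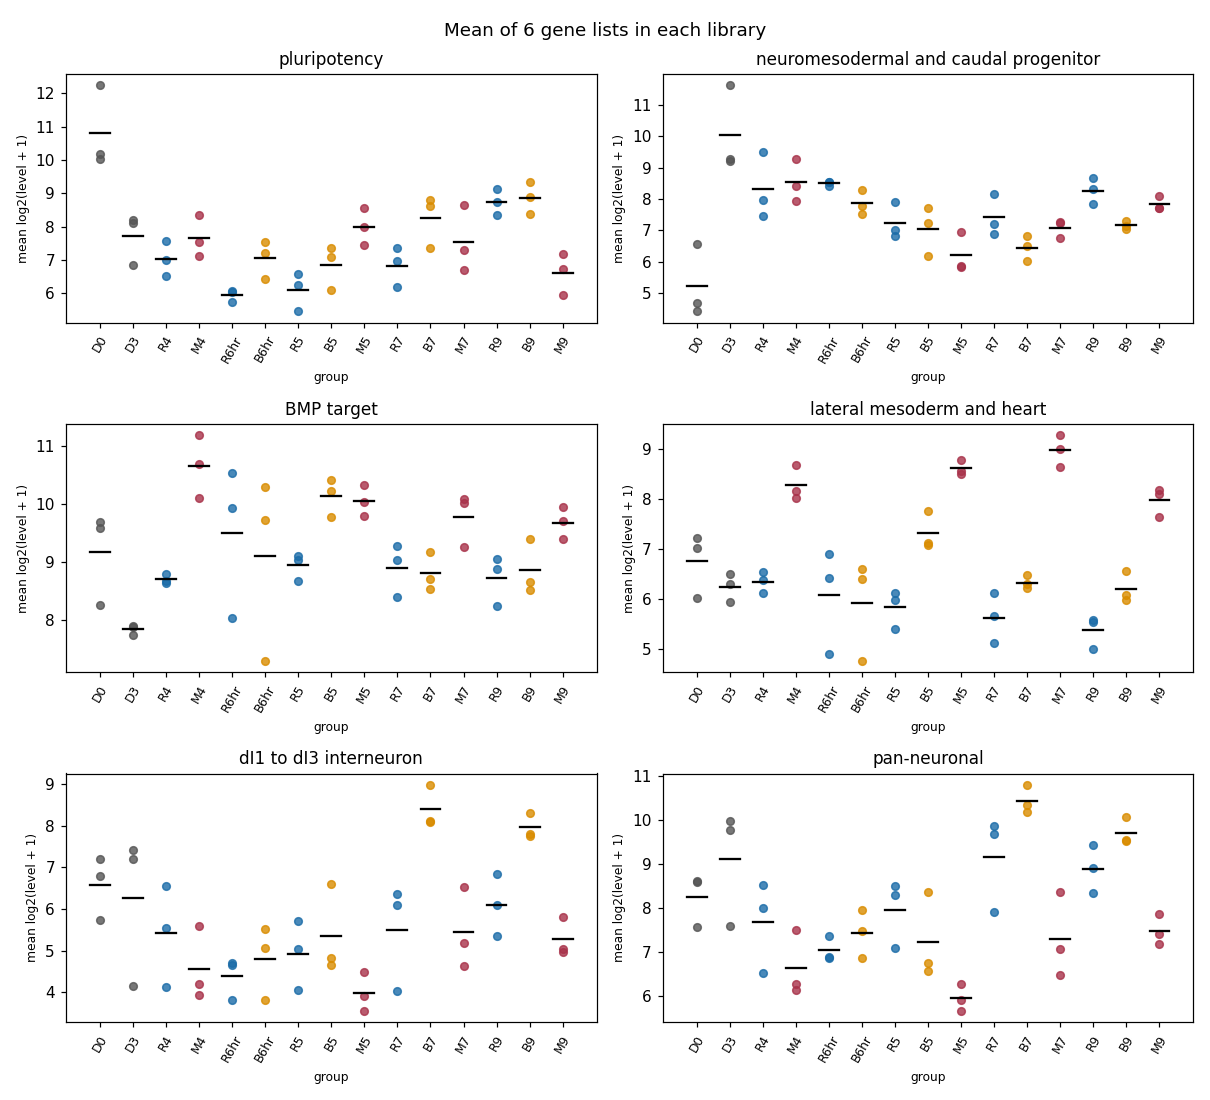
Mean log2(level + 1) of 6 gene lists in each library, by group. Points are single libraries and short bars group means. The lateral mesoderm list averages 8.62 in M5 and 5.84 in R5, the pan-neuronal list 10.45 in B7 and 7.31 in M7, and the BMP target list is spread widely within R6hr and within B6hr.

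Change with time in the R groups was read from R9 against R5. Several pluripotency and muscle genes and some neuronal genes were higher at day 9. Pou5f1 (mm10 chromosome 17, 35506018 to 35510772) rose from 127 ± 69.6 in R5 to 2616 ± 1327 in R9 (log2 change 4.39, SE 0.71, adjusted p = 2.1e-05). Gad1, the enzyme that makes the inhibitory transmitter GABA, rose from 2.77 ± 1.73 in R5 to 89.3 ± 27.5 in R9 (log2 change 4.63, SE 0.56, adjusted p = 4e-07). Other leading risen genes were Gsx1 (6.08), Trh (5.79), Kirrel2 (4.80) and Pou4f2 (4.66), and leading fallen genes Foxe3 (-7.70), Ifi203 (-6.11), Ccdc42 (-5.76), Meox1 (-4.69) and Mndal (-4.36). Among 20 pluripotency genes, 18 rose and 0 fell (18 and 0 alone), with camera adjusted p = 2.2e-08 (estimated 0.62). Esrrb (3.25, adjusted p = 6.1e-05), Utf1 (4.06, adjusted p = 0.00012) and Klf5 (2.13, adjusted p = 0.00019) rose. Out of 12 muscle genes, 10 rose and 0 fell (11 and 0 alone), with camera adjusted p = 1e-05 (estimated 0.48). Myh3 (4.53, adjusted p = 1.9e-05), Des (1.31, adjusted p = 1.9e-05) and Mylpf (2.90, adjusted p = 3.3e-05) rose. Of 22 pan-neuronal genes, 8 rose and 0 fell (8 and 0 alone), with camera adjusted p = 0.0058 (estimated 0.89). Stmn2 (2.94, adjusted p = 1.6e-05), Ina (2.11, adjusted p = 4.1e-05) and Rbfox3 (1.67, adjusted p = 0.001) rose. Among 13 FGF target genes, 7 rose and 1 fell (8 and 1 alone), with camera adjusted p = 0.012 (estimated 0.56). Fos (3.98, adjusted p = 2.1e-05), Egr1 (3.76, adjusted p = 0.00014) and Spry2 (1.32, adjusted p = 0.00066) rose, and Phlda1 (-1.31, adjusted p = 1.5e-05) fell. In limma-trend, 4392 genes passed an adjusted p under 0.05: 1983 rose and 2409 fell. Of these, 1074 and 619 changed 2-fold or more. Under quantile normalization 2198 rose and 2008 fell.

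B9 against B5 gave the same interval after sequential treatment. Many neuronal and pluripotency genes and several dI1 to dI3 genes were higher at day 9, and many cell cycle genes lower. Barhl1 rose from 6.08 ± 6.19 in B5 to 492 ± 295 in B9 (log2 change 6.32, SE 1.12, adjusted p = 4.9e-05). Top2a (mm10 chromosome 11, 98992943 to 99024189), a gene of dividing cells, fell from 20736 ± 2382 in B5 to 13221 ± 2295 in B9 (log2 change -0.66, SE 0.13, adjusted p = 0.00012). Other leading risen genes were Barhl2 (6.19), Pou3f1 (5.46), Cntn2 (5.40) and Pou4f2 (5.39), and leading fallen genes Foxe3 (-5.95), Gata5 (-5.77), Hand1 (-5.53), Ccdc42 (-5.29) and Wfikkn1 (-5.12). Among 22 pan-neuronal genes, 19 rose and 0 fell (19 and 0 alone), with camera adjusted p = 2.2e-08 (estimated 0.63). Ina (3.08, adjusted p = 1.7e-07), Stmn2 (3.80, adjusted p = 3.9e-07) and Rbfox3 (2.76, adjusted p = 2.2e-06) rose. Out of 14 dI1 to dI3 interneuron genes, 8 rose and 0 fell (8 and 0 alone), with camera adjusted p = 0.0026 (estimated 0.77). Lhx9 (4.59, adjusted p = 5.1e-05) rose with Pou4f2 and Barhl2. Out of 13 cell cycle genes, 13 fell and 0 rose (13 and 0 alone), with camera adjusted p = 3e-06 (estimated 0.63). Tyms (-1.10, adjusted p = 1.7e-06), Aurkb (-0.91, adjusted p = 1.3e-05) and Rrm2 (-0.89, adjusted p = 0.00018) fell. Out of 20 pluripotency genes, 18 rose and 1 fell (18 and 1 alone), with camera adjusted p = 3.9e-05 (estimated 0.7). Klf5 (2.08, adjusted p = 0.0002), Tcl1 (3.21, adjusted p = 0.00064), Esrrb (2.52, adjusted p = 0.00079) and Pou5f1 (3.11, adjusted p = 0.00079) rose. The test called 4899 genes with limma-trend at an adjusted p under 0.05, 2293 higher and 2606 lower in B9. Of these, 1380 and 597 changed 2-fold or more. Called members numbered 10 in the pluripotency list without B5 replicate 3.

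M9 against M5 gave this interval after combined treatment. Most endothelial and blood genes were lower at day 9, as were some pluripotency genes, and several WNT, Notch and caudal progenitor genes higher. Tek (mm10 chromosome 4, 94739289 to 94874976), an endothelial receptor gene, fell from 402 ± 76.8 in M5 to 64.2 ± 11.8 in M9 (log2 change -2.63, SE 0.29, adjusted p = 3.8e-08). Wnt8a rose from 13.9 ± 2.49 in M5 to 333 ± 64.3 in M9 (log2 change 4.48, SE 0.78, adjusted p = 5.9e-05). Other leading risen genes were Gpm6a (4.05), Fgf8 (3.91), Epha5 (3.88) and Upk1b (3.83), and leading fallen genes Hba-x (-5.05), Hbb-bh1 (-4.82), Tac2 (-3.87), Hand1 (-3.73) and Npy1r (-3.67). Among 13 endothelial and blood genes, 12 fell and 0 rose (12 and 0 alone), with camera adjusted p = 1.7e-08 (estimated 0.033). Lyl1 (-3.10, adjusted p = 2.3e-06) and Tie1 (-2.59, adjusted p = 9.7e-05) fell with the globin genes Hba-x and Hbb-bh1. Of 20 pluripotency genes, 8 fell and 0 rose (10 and 0 alone), with camera adjusted p = 0.0002 (estimated 0.75). Out of 13 WNT target genes, 8 rose and 0 fell (9 and 0 alone), with camera adjusted p = 0.00021 (estimated 0.56). Nkd2 (1.38, adjusted p = 1.5e-07), Apcdd1 (1.43, adjusted p = 1.4e-05) and Sp5 (2.71, adjusted p = 4.7e-05) rose. Out of 15 Notch pathway genes, 8 rose and 0 fell (9 and 0 alone), with camera adjusted p = 0.0007 (estimated 0.56). Lfng (2.31, adjusted p = 2.9e-05), Dll3 (2.88, adjusted p = 0.00013) and Hes7 (3.27, adjusted p = 0.00048) rose. Of 17 caudal progenitor genes, 7 rose and 0 fell (9 and 0 alone), with camera adjusted p = 0.0034 (estimated 0.75). Wnt5b (1.54, adjusted p = 0.002) rose with Fgf8 and Sp5. Past an adjusted p under 0.05 in limma-trend lay 2897 genes, with 1615 risen, 1282 fallen, and 797 and 472 of them changed 2-fold or more. Under quantile normalization 1415 rose and 1601 fell. Called members numbered 2 to 5 in the pluripotency list without M5 replicates 1 or 2 or M9 replicates 1 or 2, 5 in the WNT target list without M5 replicate 1 and 4 in the caudal progenitor list without M5 replicate 1. Called list members numbered 5 in the pluripotency list with adjustment over all genes the authors tested.

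The 24 h BMP4 effect from day 3 (M4 against R4) was set against that from day 4 (B5 against R5). Timing and prior RA were not separated. Some surface ectoderm genes had a more positive effect with BMP4 from day 3, and some paraxial mesoderm and dorsal progenitor genes had a more negative effect then. Trp63 (mm10 chromosome 16, 25683763 to 25892102) had effects of 4.85 and 0.13, which differed by 4.72 (log2 change 4.72, SE 0.68, adjusted p = 0.00016). Foxd3 had effects of -0.01 and 4.87 (log2 change -4.88, SE 1.19, adjusted p = 0.028 for the difference). Other genes with the largest positive differences were Filip1 (3.97), Wnt9b (3.93), Cldn8 (3.56) and Wnt7a (3.52), and with the largest negative differences Rfx4 (-5.20), Tbx18 (-5.12), Cer1 (-4.84) and Shox2 (-4.01). Of 16 surface ectoderm genes, 4 had a positive and 0 a negative difference (9 and 0 alone), with camera adjusted p = 1.3e-15 (estimated 0.033). Wnt6 (3.45, adjusted p = 2.3e-09), Krt8 (1.92, adjusted p = 0.00021) and Krt18 (2.02, adjusted p = 0.002) stood with Trp63, Wnt6 with effects of 2.06 and -1.39. Of 16 paraxial mesoderm genes, 0 had a positive and 2 a negative difference (0 and 7 alone), with camera adjusted p = 3e-06 (estimated 0.37). Pax9 (-3.77, adjusted p = 0.00086) stood with Tbx18. Among 18 dorsal neural progenitor genes, 0 had a positive and 2 a negative difference (0 and 6 alone), with camera adjusted p = 2.8e-05 (estimated 0.63). Zic2 (-2.90, adjusted p = 0.002) and Zic5 (-3.06, adjusted p = 0.005) passed, and Olig3 (log2 change -5.11, SE 1.46, adjusted p = 0.076) did not. The difference passed in 127 genes at an adjusted p under 0.05 in limma-trend, 66 of them positive and 61 negative. With quantile normalization 79 were positive and 84 negative. Called members numbered 4 in the paraxial mesoderm list without M4 replicate 3. Without 1 library the call ended for Foxd3 without B5 replicates 1 or 2 or M4 replicates 2 or 3 or R4 replicates 1 or 3 or R5 replicates 1 or 3 (adjusted p = 0.051 to 0.11). Within the compared libraries alone 54 genes were called, and the call ended for Foxd3 (adjusted p = 0.19), Filip1 (0.072), Cldn8 (0.071), Cer1 (0.056) and Shox2 (0.054). The call also ended for Cer1 (adjusted p = 0.052) with a pseudocount of 0.1. Past 0.05 (adjusted p) came Olig3 (0.045) with quantile normalization. Called list members numbered 4 in the dorsal neural progenitor list with quantile normalization.

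**Figure D3:**
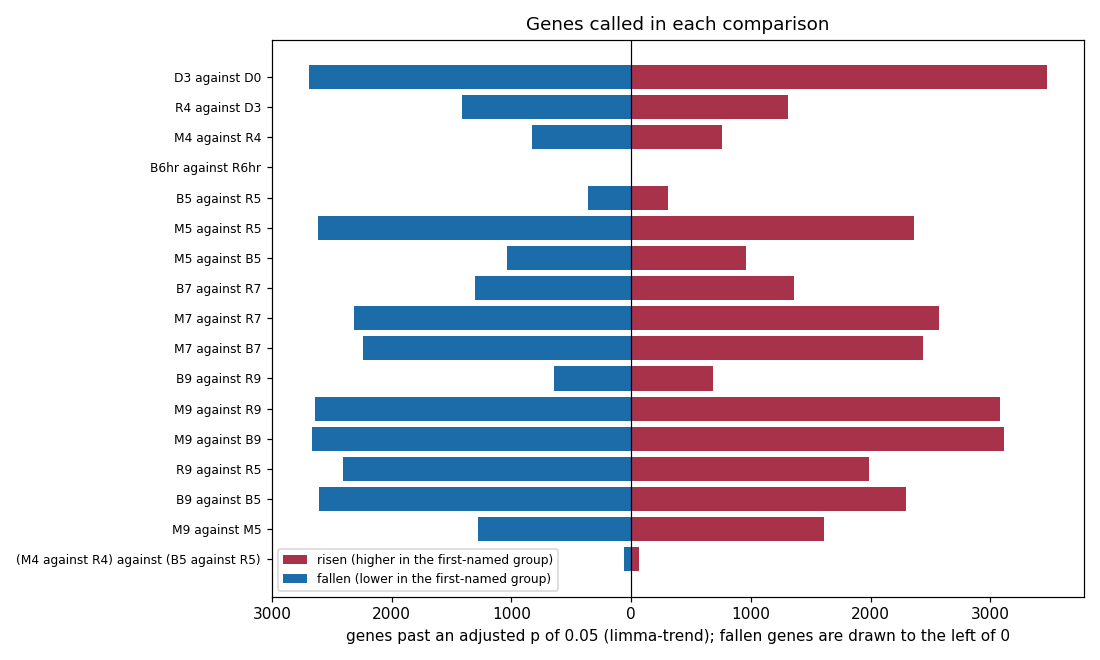
Number of genes past an adjusted p of 0.05 in limma-trend in each comparison, with risen genes to the right of 0 and fallen genes to the left. The bars range from 2 genes in B6hr against R6hr to 6161 in D3 against D0.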

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

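The tests on scale factors, swaps, shared replicate numbers and mixing into D3 replicate 1 were chosen after the results they bear on were seen, while those on D3 replicate 1 as a source of mixing, implied share and other splits were chosen before. The 24 h effects of BMP4 from day 3 and from day 4 differed in 127 genes by the test of the difference itself. The named genes with a positive difference were Trp63 (4.72), Filip1 (3.97), Wnt9b (3.93), Cldn8 (3.56) and Wnt7a (3.52), and with a negative difference Rfx4 (-5.20), Tbx18 (-5.12), Foxd3 (-4.88), Cer1 (-4.84) and Shox2 (-4.01), as log2 differences. Of 100 splits of the libraries within the pairs, 8 gave as many genes, the real one included, and the highest other gave 1518, so chance cannot be excluded by this count. Of the 18 splits that leave 1 pair as labelled, and so keep that pair's whole effect, 7 gave as many. Of the 81 that divide both pairs anew, 0 did.

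D3 replicates 2 and 3 held less of the caudal progenitor genes and more of the pan-neuronal genes than replicate 1 (median log2 differences of -2.41 and 2.49). A library-wide scale factor is argued against, since the list medians lay 4.9 apart while all genes shifted by 0.05, and so is a swap of replicate 1 with another library, since the best outside match to replicates 2 and 3 correlated at 0.56, against 0.89 between them. Mixing of 1 other library into replicate 1, if otherwise like replicates 2 and 3, is argued against for the caudal genes. In replicate 1, 9 of 17 lay over 2-fold above every other library, as did 0.3% of genes averaging 100 or more. Replicates 2 and 3 as RNA like replicate 1's mixed with 1 other library's stays open. With the best of 42 sources, B9 replicate 1, 1.9% of 8041 genes lay over 2-fold outside both sources, and with the worst 10.8%. The dI1 to dI3 list mean (log2 level) was 4.16, 7.2 and 7.42 in D3 replicates 1, 2 and 3, and 8.31 in B9 replicate 1. Barhl1 stood at 12.8, 249 and 450 in D3 replicates 1, 2 and 3, and at 831 in B9 replicate 1. A difference between cultures at the same stage was not tested.

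The BMP target list mean (log2 level) was 8.03, 9.94 and 10.54 in R6hr replicates 1, 2 and 3, and 7.29, 9.72 and 10.30 in B6hr. A plain swap of labels between the 2 groups is argued against, since it needs 3 of the 6 libraries above every R4 and R5 library (highest 9.11), and 4 were. A difference shared by libraries of the same number stays open. The correlations (same-number lowest 0.19, other highest 0.15) singled out these groups, so they do not test it. What the numbers share (a differentiation, a handling day, or BMP4 reaching both cultures) was not tested.

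Pluripotency genes were higher at day 9 than at day 5 in the R and B groups. A library-wide scale factor is argued against, since the list median exceeded that of all genes by 2.86 in R and 2.33 in B (log2). RNA of undifferentiated cells at 1 share of the library stays open. Genes enriched in D0 implied median shares of 15.2% in R (223 genes) and 18.2% in B (144). Upper to lower quartile ratios were 2.6 and 2.5. The shares depend on D0, where Pou5f1 varied (3064, 2678 and 22336). A change of the differentiating cells was not tested.

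With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In 14 comparisons of 2 groups only 1 of the 10, the real one, gave as many genes. The highest other split gave 282 against 6161 in D3 over D0 and 544 against 4882 in M7 over R7, and at most 2 in the other 12. In R4 over D3, 2 of 10 splits gave as many, the other giving 3075 against 2722. In B6hr over R6hr, 3 of 10 gave as many, and the highest gave 172 against 2, which points to a structure of these samples. The 3 other splits that part every same-numbered pair gave 0 genes, and the splits with 172 and 42 genes put libraries of the same number on 1 side.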

How the results depend on the processing

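No named gene changed direction while past the threshold under any alternative run, and the cause of the changes in number below was not tested. Of the alternatives fixed at the outset, a second count test, its size factors and a filter on counts were not run because the values are not counts. Dropping the filter moved nothing. Alternatives listed as added were chosen after seeing the data. The depth of each library is unknown, so what it limits cannot be stated. Counts that stayed within 1.5 times are not listed.

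At an adjusted p under 0.1 the number of genes was 7 in B6hr over R6hr, 1160 in B5 over R5, 2074 in B9 over R9 and 228 in the difference of effects. With 2-fold or more it was 3177 in D3 over D0, 1126 in R4 over D3, 789 in M4 over R4, 318 in B5 over R5, 2391 in M5 over R5, 972 in M5 over B5, 1176 in B7 over R7, 2448 in M7 over R7, 2073 in M7 over B7, 560 in B9 over R9, 2567 in M9 over R9, 2220 in M9 over B9, 1693 in R9 over R5, 1977 in B9 over B5 and 1269 in M9 over M5. With the compared libraries alone it was 4001 in D3 over D0, 1046 in R4 over D3, 364 in M4 over R4, 847 in B6hr over R6hr, 97 in B5 over R5, 1020 in M5 over B5, 1475 in B7 over R7, 3238 in M7 over R7 and 54 in the difference of effects. In B6hr over R6hr it was 0 with a pseudocount of 0.1, 9 with 5, 1 with quantile normalization, 0 adjusted over all genes the authors tested, 12 in the authors' deposited table and 0 without number 1 of both groups. With array weights, which ran from 0.12 to 8.69, it was 6932 in R4 over D3, 3914 in M4 over R4, 3961 in B6hr over R6hr, 2196 in B5 over R5, 7713 in M5 over R5, 4105 in M5 over B5, 6215 in B7 over R7, 7357 in M7 over R7, 7296 in M7 over B7, 5024 in B9 over R9, 5818 in M9 over M5 and 952 in the difference of effects.

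With the replicate block over all libraries, the number of genes stayed within 1.5 times in every comparison, 0 named genes lost their call, and called pan-neural progenitor genes in B5 over R5 numbered 2. With the block within the compared libraries the number was 3081 in D3 over D0, 161 in R4 over D3, 340 in M4 over R4, 2902 in B6hr over R6hr, 2 in B5 over R5, 0 in B7 over R7, 1274 in M7 over R7, 2214 in B9 over R9, 1034 in R9 over R5 and 46 in the difference of effects. Outside the 6 h groups the pairing rule was not met, which leaves pairing open there.

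Leaving out each library in turn gave 5675 to 5977 genes in D3 over D0, 1841 to 3779 genes in R4 over D3, 876 to 1518 genes in M4 over R4, 0 to 10 genes in B6hr over R6hr, 196 to 897 genes in B5 over R5, 3994 to 4807 genes in M5 over R5, 1026 to 1996 genes in M5 over B5, 1441 to 2155 genes in B7 over R7, 4254 to 4639 genes in M7 over R7, 3584 to 4198 genes in M7 over B7, 556 to 1141 genes in B9 over R9, 4527 to 5272 genes in M9 over R9, 4395 to 5400 genes in M9 over B9, 3171 to 4092 genes in R9 over R5, 3409 to 4973 genes in B9 over B5, 1998 to 2534 genes in M9 over M5 and 89 to 138 genes in the difference of effects. Named genes stayed on their side of the threshold in 2258 cases and lost their call in 99.

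Named genes lost their call in 6 cases with a pseudocount of 0.1, 1 with 5, 3 with quantile normalization, 20 with the compared libraries alone, 7 adjusted over all genes the authors tested, 72 with the block within the compared libraries, 1 with array weights, 1 in the authors' deposited test and 2 without number 1 of the 6 h groups. In 11 comparisons the balance of risen and fallen genes turned with quantile normalization. Of 175 list tests called with the preset correlation, 3 held with an estimated one (median 0.37): surface ectoderm in M4 over R4 and in the difference of effects, and endothelium and blood in M9 over M5. Fry called 164 list tests with a direction.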

Other observations

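M5 over R5 also differed in gene groups not described above. Among 15 Hox 1 to 5 genes, 15 fell and 0 rose (15 and 0 alone), with camera adjusted p = 8.2e-06 (estimated 0.63). Out of 13 p53 target genes, 10 fell and 0 rose (10 and 0 alone), with camera adjusted p = 1.5e-05 (estimated 0.48). Among the fallen was Hoxb4 (-2.30, adjusted p = 4.2e-05). The Hox 1 to 5 list was also read in B7 over R7. Out of 15 Hox 1 to 5 genes, 11 fell and 0 rose (12 and 0 alone), with camera adjusted p = 3.3e-06 (estimated 0.63). Called members there numbered 5 in the Hox 1 to 5 list without B7 replicate 1.

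The endoderm list (13 measured genes) and the ventral spinal cord list (18) were not called by camera in any of the 17 comparisons. In M5 over R5, 5 endoderm genes rose and 2 fell, and 7 ventral genes fell and 4 rose. The mitochondrially encoded list had 0 members in the table. By correlation of gene-centred levels, 38 libraries were nearest to one of their own group and 7 to another. In the authors' deposited table, at a false discovery rate under 0.05, 584 genes differed between R4 and R6hr, 690 between R4 and B6hr, 1603 between R6hr and R5, and 2355 between B6hr and B5.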
